A study of Zea mays with 24 samples.

How the data were processed

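Total RNA from maize (Zea mays) coleoptilar nodes was profiled on 24 one-colour Agilent arrays labelled with Cy3. Per the labels, the nodes came from wild-type (WT) and rtcs mutant seedlings 0, 2 and 4 days after the node emerged. Each of the 6 groups had 4 biological replicates, each an RNA extract from a pool of nodes. Per the file headers, the deposited scanner files hold spot intensity from Agilent Feature Extraction 9.5.3.1 with protocol GE1-v5_95_Feb07. Spatial detrending took the place of background subtraction (BGSubMethod 7), multiplicative detrending was on and surrogates were used for dim spots, per the file headers. The submitters' processing notes name the same software. The deposited value table of the series holds intensity on a linear scale, without centring, with column medians from 12.3 to 33.7.

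Each array carried 105010 spots, of which 1025 were positive and 300 negative control spots. The 103685 other spots held 103680 probes of 60 bases, 5 of them spotted in duplicate. The share of probes well above background ran from 57.5% to 70.8% per array, with a median of 63.2%. Between 2 and 47 spots per array carried an outlier flag, and 2 spots in all were saturated. For arrays, the number of replicates limits the precision, and a probe near background has only a bound on its level.

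Control spots were left out, outlier-flagged spots were set missing, and values under 1 were set to 1. The processed signal was taken to log2, each array's 75th percentile over all non-control probes was subtracted, and spots of the same probe were averaged. A value of 0 is thus the 75th percentile of its array. A probe was tested where it was well above background on at least 3 arrays of at least 1 group. That left 69526 probes under the scanner-file assignment and 69698 under the value-table assignment. A linear model with 6 group means over all 24 arrays was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and the Benjamini-Hochberg method was applied over all probes tested. An adjusted p under 0.05 counted as a call. Every adjusted p in the text comes from limma, from this fit unless an alternative is named. The tests were two-sided.

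The arrays can be assigned to samples in 2 ways, and these disagree. In the scanner-file assignment each scanner file belongs to the sample it was deposited under. The slide barcode in the file equalled the one in the sample's label for 24 of 24 files. In the value-table assignment each scanner file belongs to the sample named by the value-table column that holds its values. For each column, at least 99.53% of values above a signal of 1000 were found in 1 scanner file within 0.006, and at most 3.65% in any other. That file was the column's own sample's file for 2 columns and another sample's file for 22. The columns paired with the files 1 to 1. The scanner-file assignment was the one fixed before the data were examined, and the value-table assignment was added after seeing the data. The comparisons and the alternatives fixed before the data were examined were run under both where they could be fitted, apart from the value table as deposited. Named probes, single sessions, slides left out, whole slides exchanged, shared sequence and GC content were examined under the value-table assignment alone. The table's rows could not be used throughout: 15 columns that end in a 0 hold, after row 53236, the probe of the following row of the other 9 columns (13757 of 13758 rows that could be compared). Scanner values were therefore used for both assignments.

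The comparisons fixed before the data were examined were rtcs against WT on each day and over the mean of the days, the genotype by day interaction, and the steps between successive days in each genotype. Day 4 against day 0 in each genotype was added after seeing the data. The alternatives were quantile normalization, median centring, another probe set for the percentile, normexp background correction with an offset of 50, the value table, looser and stricter filters, outlier-flagged spots kept, slide as a random or fixed block, replicate number as a block, only the arrays compared, array weights, a trended and robust prior, and each array left out. Extraction session as a block, the sessions taken separately, and slides left out were added after seeing the data. Normexp correction started from the mean spot signal and the local background median, not the processed signal, and so left out the detrending and surrogates. The consensus correlation for slide used every 5th probe. Splits that exchange whole slides between the genotypes, each array keeping its day and each group 4 arrays, were added after seeing the data, with 100 of 108 possible splits used. The session of an array is the day its image was processed, in order, from the file headers.

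No probe could be given a gene name. The files pair the probes with array or contig identifiers only, and 0 of 103680 matched the reference gene table (assembly Zm-B73-REFERENCE-NAM-5.0). The 32 gene lists fixed before the data were examined, and the check of the RTCS transcript in each sample, were therefore not analysed here. The rule for named genes required gene names and so chose none. The probes named below were chosen after their values were seen. They are the 2 with the largest rise and the 2 with the largest fall among called probes that were well above background on every array compared and whose groups did not overlap. The single probe called for WT day 2 against day 0 is also named.

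The fit was tested on simulated data for 3 comparisons under each assignment, with 200 changed probes. For rtcs against WT on day 0 under the value-table assignment, with 69442 probes, it recovered 22% of probes changed 2-fold and 68% of those changed 4-fold, and called 3 unchanged probes. For rtcs against WT over the mean of 3 days, on the same probes, the shares were 62% and 88%, with 8 unchanged probes called. The simulated noise was independent between arrays, whereas the consensus correlation within a slide of the real arrays was 0.41 under this assignment. The simulation therefore does not measure false calls that shared slides could cause. Sequence overlaps, tests and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.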

Results

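Transcript levels were measured in the coleoptilar node, the shoot node from which the first crown roots of a maize seedling arise. The rtcs mutant (rootless concerning crown and seminal roots) lacks a LOB-domain transcription factor and forms no crown or seminal roots. WT and rtcs nodes were compared on days 0, 2 and 4 after the node emerged, with 4 biological replicates per genotype and day. The 24 arrays lay on 13 slides, 11 of them with 2 arrays. Between 57.5% and 70.8% of the 103680 probes on an array were well above background. Probes are named by their array identifiers, because the files do not pair them with genes.

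The deposited files assigned the arrays to samples in 2 ways that agreed for 2 of 24 arrays. The slide numbers in the labels and the scanner files gave one assignment, and the columns of the value table gave the other. Under the scanner-file assignment, 6 of the 11 slides with 2 arrays held 1 group and 5 held both genotypes. Under the value-table assignment, all 11 held 1 genotype on 2 different days, so that no slide held both genotypes. The counts of each comparison are given under both assignments, and the named probes and the fits within sessions under the value-table assignment alone. Which samples the values describe depends on which one is right.

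**Figure D1:**
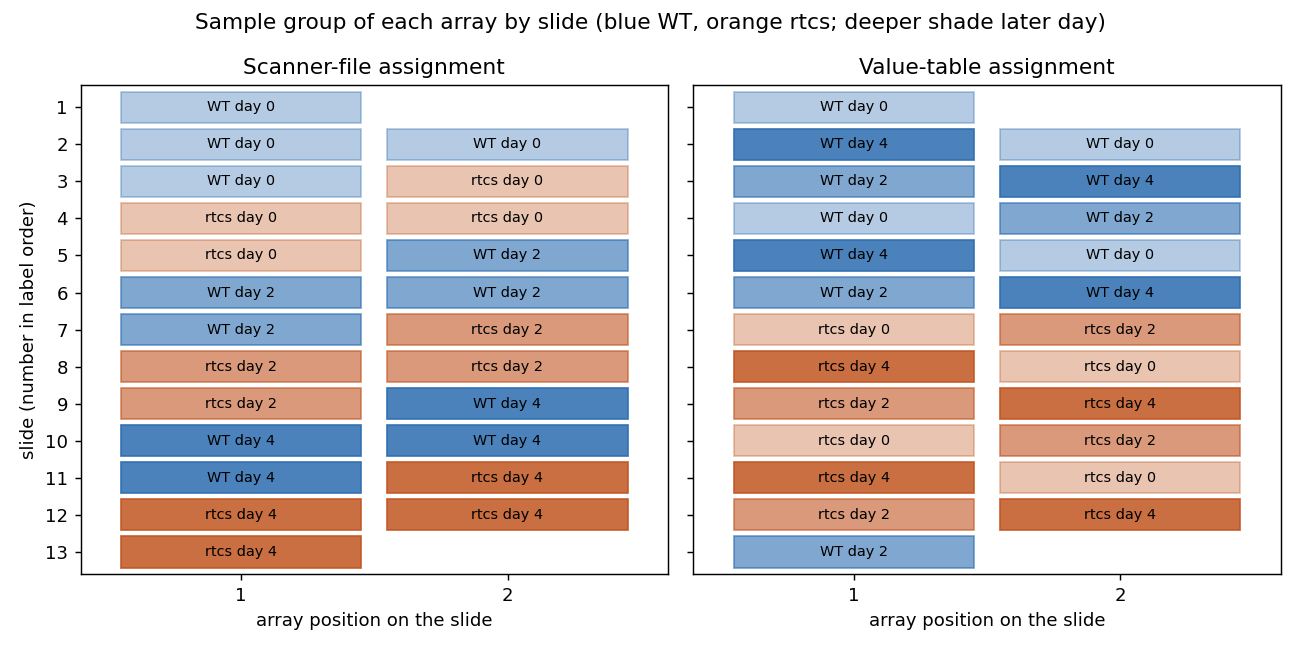
The group of each array is drawn by slide (vertical, 13 slides) and position on the slide (horizontal), with WT in blue and rtcs in orange. In the right panel each slide with 2 arrays holds 1 genotype, and in the left panel 5 slides hold both.

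The first principal component, over 51217 probes well above background on all arrays, held 20.3% of the variance and the second 18.2%. On the first component the 12 arrays assigned to WT by the value table lay between -91.5 and -3.3, and the 12 assigned to rtcs lay between 28.8 and 74.0. Under the scanner-file assignment, arrays of WT day 2 and of rtcs day 4 fell on both sides of 0. The median correlation between arrays of a group was 0.968 under the scanner-file assignment and 0.969 under the value-table assignment, against 0.960 between groups in both.

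**Figure D2:**
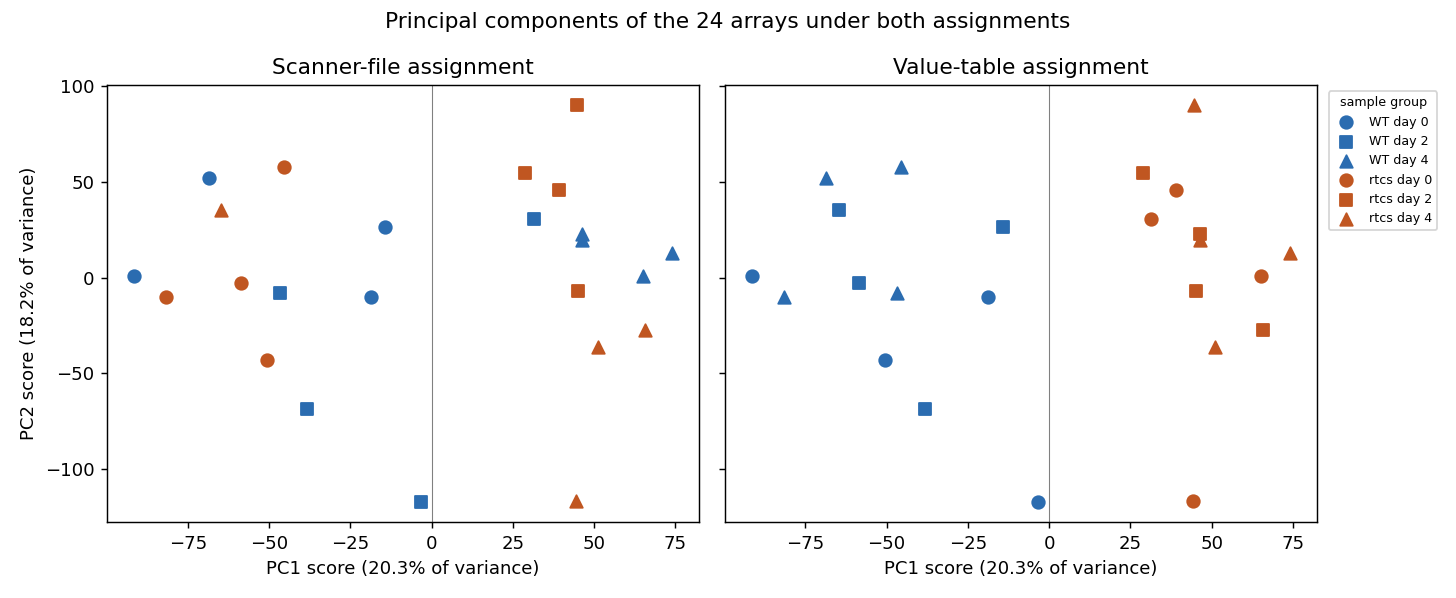
Each point is 1 array, placed by its scores on PC1 (20.3% of variance) and PC2 (18.2%), with colour for genotype and shape for day. In the right panel all WT arrays lie at or below -3.3 on PC1 and all rtcs arrays at or above 28.8.

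The comparison of rtcs with WT asks which transcripts differ in a node that forms no crown roots. With the scanner-file assignment limma called 0 probes over the mean of 3 days, with 3196 at an unadjusted p under 0.05. On normexp-corrected values it called 34294 higher and 8194 lower in rtcs, where the median over all tested probes shifted by 0.29 on the log2 scale. With the value-table assignment, 7079 probes were higher and 7424 lower in rtcs, which was 20.8% of the probes tested. Their median log2 difference was 0.61 for the higher and -0.68 for the lower probes. At 2-fold or more 2015 called probes were lower in rtcs and 1041 higher, and at 4-fold or more 559 were lower and 119 higher. In 339 of the called probes the 12 WT arrays and the 12 rtcs arrays did not overlap. Among 100 splits that exchanged whole slides between the genotypes, the real one included, the highest other gave 34 such probes. The fit took arrays of 1 slide as independent, here and for the probes named next. With slide as a random block 7915 probes were called over the mean of 3 days under the value-table assignment.

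Probe P1000281831 (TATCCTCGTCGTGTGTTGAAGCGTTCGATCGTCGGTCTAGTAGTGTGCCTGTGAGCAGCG) was higher in rtcs by 4.70 on the log2 scale over the mean of 3 days under the value-table assignment (SE 0.26, adjusted p = 1.7e-10), with non-overlapping arrays. On day 0 its normalized log2 signal was 2.06 ± 1.04 in rtcs and -3.35 ± 0.23 in WT (SD, n = 4). Probe P1000295951 (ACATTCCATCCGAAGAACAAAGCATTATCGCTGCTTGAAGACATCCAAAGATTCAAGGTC) was higher by 3.89 (SE 0.45). Its level in rtcs was 2.23 ± 0.11 on day 2 and 2.04 ± 0.11 on day 4 (SD, n = 4), against -1.30 ± 1.90 and -1.93 ± 1.41 in WT. Probe P1000292216 (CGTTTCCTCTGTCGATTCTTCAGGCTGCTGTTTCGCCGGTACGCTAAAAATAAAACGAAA) was the probe with the largest fall of this kind, with a log2 difference of -6.76 (SE 0.45, adjusted p = 2.4e-09). It measured 5.91 ± 0.78 in WT and -1.33 ± 0.91 in rtcs on day 2 (SD, n = 4). Probe P1000242779 (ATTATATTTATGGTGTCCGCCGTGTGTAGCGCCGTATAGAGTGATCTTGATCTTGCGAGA) differed by -4.87 (SE 0.36), from 2.94 ± 0.38 in WT to -2.70 ± 0.85 in rtcs on day 2. On normexp-corrected values the log2 differences of P1000281831, P1000295951, P1000292216 and P1000242779 lay nearer 0, at 1.83, 2.08, -4.82 and -2.34.

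**Figure D3:**
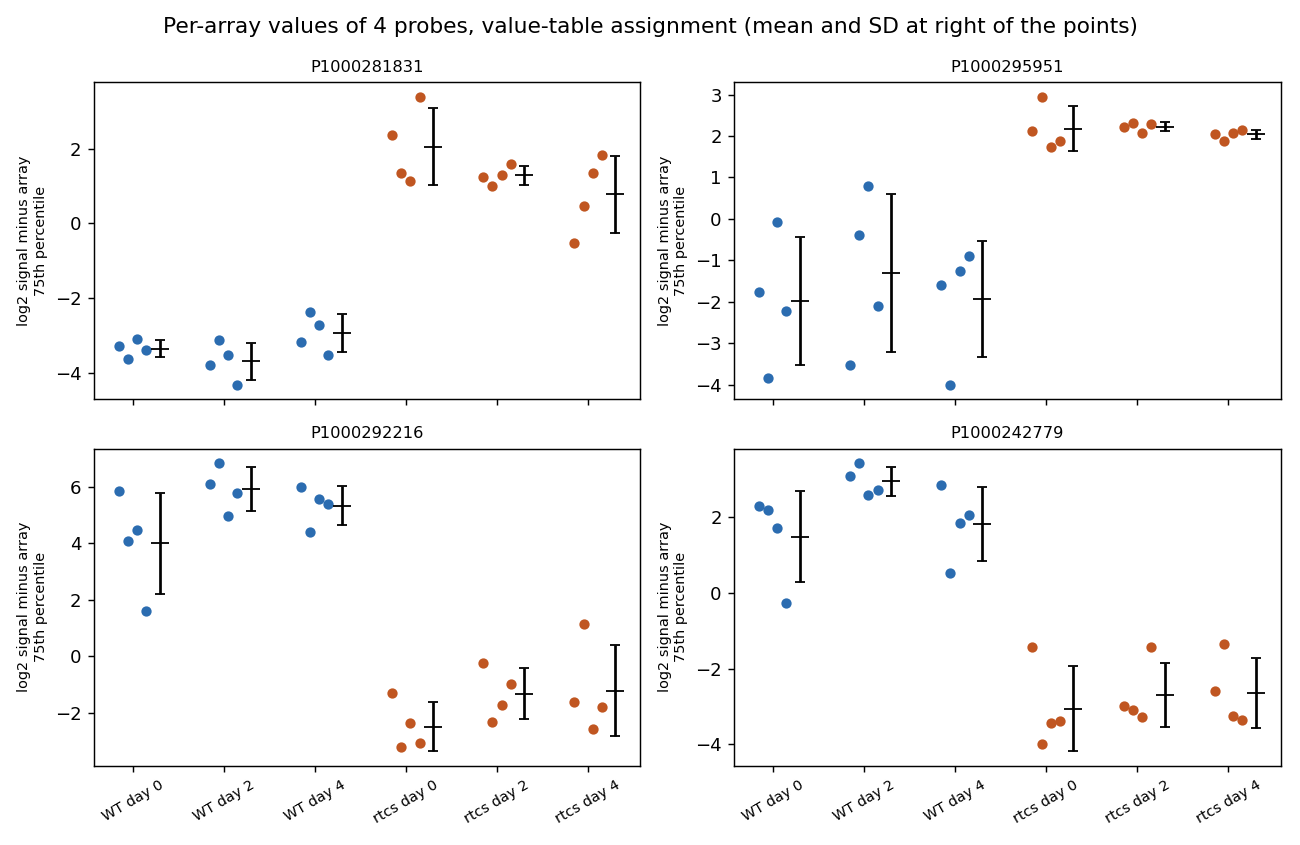
Points are the normalized log2 signals of single arrays for 4 probes by group under the value-table assignment (0 is the 75th percentile of the array), with the mean and SD of each group beside them. P1000281831 and P1000295951 lie higher in all rtcs groups, P1000292216 and P1000242779 lower.

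Among the probes called over the mean of 3 days under the value-table assignment, 19 were well above background on all 12 arrays of one genotype and on none of the other. Of these, 13 were seen in rtcs and 6 in WT. Their levels differed by at least 1.63-fold to at least 425-fold, with a median bound of 6.71-fold. These bounds set the mean of the bright genotype against the lowest signal that was well above background on each array of the dim one, or the probe's own signal where that was higher. Under the scanner-file assignment 0 probes were of this kind.

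The scanner-file counts on single days depended on the fit. On day 0 limma called 0 probes, with 5570 at an unadjusted p under 0.05, and on day 4 it called 0, with 9979. On day 2 it called 2 higher and 52 lower in rtcs. This total of 54 became 5380 without WT day 2 replicate 4, and 2, 3 and 2 without the other arrays of WT day 2. The value table assigned WT day 2 replicate 4 to rtcs, and it scored 31.4 on the first principal component. The other arrays of WT day 2 were assigned to WT, with scores from -46.7 to -3.3. The total of 54 was also moved by other settings. It was 0 in limma on normexp-corrected values and with slide as a fixed block, with 26505 and 2285 at an unadjusted p under 0.05. Array weights gave 7042 on day 2 and 7825 on day 4, and session as a block gave 530 on day 2. The interaction of genotype and day had 180 calls. Leaving out 1 array gave 5722 without WT day 2 replicate 4. It gave 0 without WT day 2 or day 4 replicate 1, 2 or 3, rtcs day 0 replicate 3, rtcs day 2 replicate 2 or rtcs day 4 replicate 1, with 11590 to 13742 at an unadjusted p under 0.05 in limma. Slide as a random or fixed block gave 0, with 11371 and 4553 at an unadjusted p under 0.05. Across probes, which are not independent replicates, the genotype differences of days 2 and 4 correlated at -0.53, and those of day 0 with days 2 and 4 at -0.13 and 0.09.

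The value-table assignment gave 800 probes higher and 1016 lower in rtcs on day 0, 147 higher and 433 lower on day 2, and 913 higher and 1723 lower on day 4. Of the 3965 probes called on 1 day or more, 3644 had the same sign on all 3 days. On all 3 days 298 probes were called, against 0 in every other one of the 100 splits that exchanged whole slides, and all 298 kept 1 direction, with 78 higher and 220 lower in rtcs. The days share slides under this assignment, and across probes the genotype difference on day 0 correlated with that on day 2 at 0.70 and with that on day 4 at 0.62, and days 2 and 4 correlated at 0.76. The interaction had 0 calls in limma, with 1955 probes at an unadjusted p under 0.05, and 6 calls with slide as a random block, 2 on quantile-normalized values, 2 with array weights and 1 with median centring. Leaving out 1 array moved the total of day 0 from 1816 to between 751 (without rtcs day 0 replicate 1) and 2901 (without rtcs day 0 replicate 4). It moved day 2 from 580 to as few as 263 (without rtcs day 2 replicate 2) and day 4 from 2636 to as few as 1009 (without rtcs day 4 replicate 3).

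Background correction and batch moved the genotype counts of the value-table assignment. Normexp correction reduced the count over the mean of 3 days to 359 higher and 2088 lower, and the totals of days 0, 2 and 4 to 29, 25 and 112. It also started from the mean spot signal and local background in place of the processed signal, and so left out the detrending and surrogates. It added an offset of 50, above the column medians of 12.3 to 33.7. The parts of the input signal and of this offset were not tested. On day 0, scaling to the percentile of probes well above background on all arrays gave 1100 higher and 736 lower. The total of day 0 was 111 with only the arrays compared and 1041 without the filter. That of day 2 was 268 with session as a block and 2582 with array weights. That of day 4 was 1041 with session as a block, 4106 with slide as a random block and 7048 with array weights. Session 1 held 9 WT and 2 rtcs arrays and session 2 held 2 WT and 10 rtcs arrays, so that session and genotype were largely aligned. The 2 rtcs arrays of session 1 were from days 0 and 2 on slide 7. The 2 WT arrays of session 2 were from days 2 and 4 on slide 6. With the session as a block 8873 probes were called over the mean of 3 days. Between the genotypes 858 were called within session 1 and 1322 within session 2, each with 1 genotype on a single slide and not on all days. Of the probes called over all arrays, 96.0% had the same sign within session 1 and 97.6% within session 2. These arrays are part of the arrays that gave the calls. The genotype differences of the 2 sessions correlated at 0.47 across probes. With slide as a random block 7915 were called. A fixed block for slide could not be fitted to the genotype comparisons, because each slide held 1 genotype. Exchanging whole slides gave at most 5288 calls over the mean of 3 days, against a real 14460. This argues against effects of single slides as the whole cause. A batch shared by the slides of a genotype cannot be told apart from genotype.

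**Figure D4:**
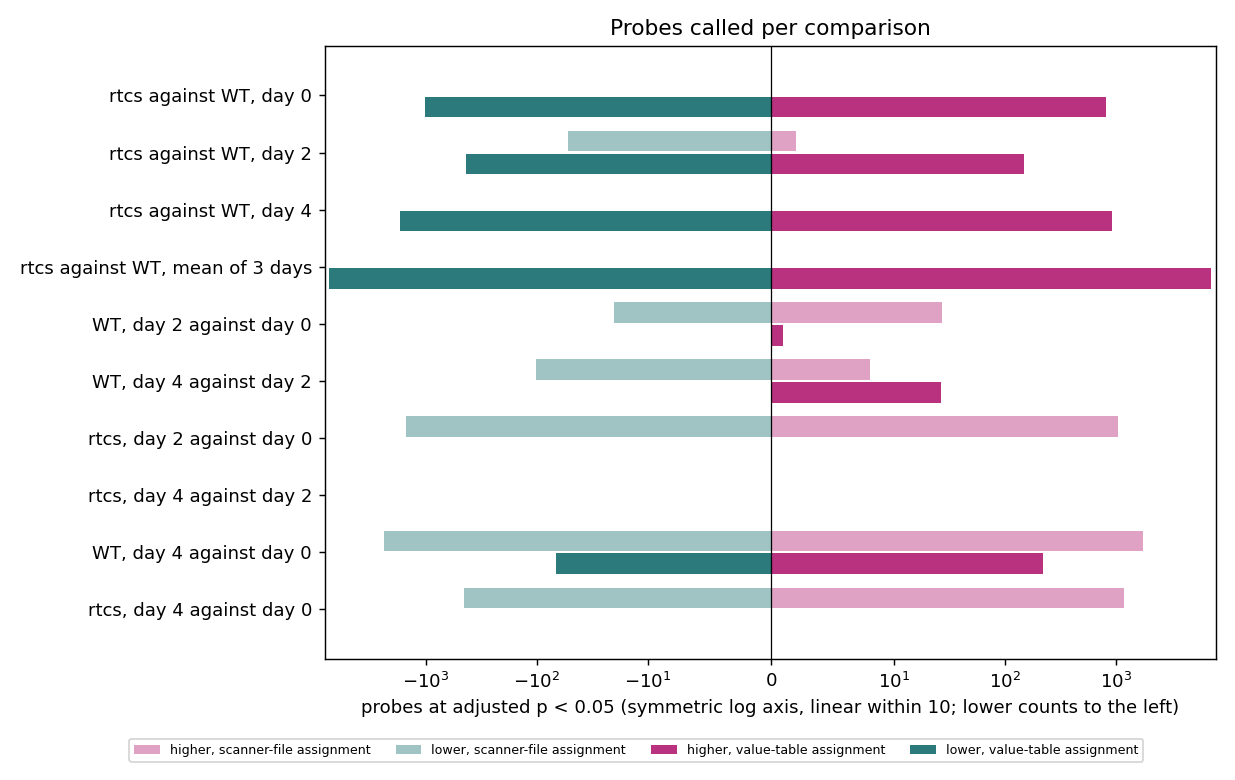
Bars count probes at adjusted p under 0.05 per comparison on a symmetric log axis, higher to the right and lower to the left, with pale bars for the scanner-file and dark bars for the value-table assignment. Each genotype comparison has more calls under the value-table assignment, and each day comparison more under the scanner-file assignment except rtcs day 4 against day 2, with 0 under both.

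The comparison of days within a genotype follows the node as it develops. With the scanner-file assignment, 1729 probes rose and 2387 fell in WT from day 0 to day 4, and 1178 rose and 453 fell in rtcs. From day 0 to day 2, 27 rose and 20 fell in WT, and 1040 rose and 1497 fell in rtcs. From day 2 to day 4, 8 rose and 101 fell in WT, and limma called 0 in rtcs, with 12431 at an unadjusted p under 0.05. The difference between the genotypes in day 4 against day 0 had 0 calls in limma, with 6739 at an unadjusted p under 0.05. The value table assigned every scanner-file array of WT day 0 and of rtcs day 0 to WT. It assigned every array of WT day 4 and of rtcs day 2 to rtcs. The counts for WT day 4 against day 0 and rtcs day 2 against day 0 thus also compare the value-table genotypes. Day and genotype cannot be told apart there while the assignment is open.

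These day counts moved with background correction, scaling, slide and single arrays. Normexp correction gave 1 call for rtcs day 2 against day 0, 0 for rtcs day 4 against day 0, with 1855 at an unadjusted p under 0.05 in limma, and 420 for WT day 4 against day 0. With only the arrays compared limma called 0 for rtcs day 4 against day 0, with 11132 at an unadjusted p under 0.05. For rtcs day 4 against day 2 array weights gave 4803 calls and session as a block 2241. For WT day 2 against day 0, quantile normalization gave 133 higher and 37 lower and median centring 83 and 24. Quantile normalization gave 1656 higher and 1310 lower for rtcs day 2 against day 0 and 2803 higher and 2346 lower for WT day 4 against day 0. For rtcs day 4 against day 0, median centring gave 2426 higher and 340 lower, and the percentile over probes well above background on all arrays gave 565 higher and 509 lower. With slide as a fixed block limma called 0 probes for day 2 against day 0 and for day 4 against day 0 in WT and in rtcs. Only the 5 slides that held both genotypes link the groups in this fit, so it has little power. Leaving out WT day 2 replicate 4 raised the WT count of day 2 against day 0 from 47 to 2037 and that of day 4 against day 2 from 109 to 3394. Without WT day 2 replicates 1, 2 and 3 the first was 9, 5 and 4 and the second 4, 2 and 4. Leaving out rtcs day 4 replicate 4 raised the rtcs count of day 4 against day 2 from 0 to 1142 and that of day 4 against day 0 from 1631 to 5585. The value table assigned rtcs day 4 replicate 4 to WT and the other arrays of its group to rtcs. It likewise assigned WT day 2 replicate 4, alone of its group, to rtcs. The lowest counts without 1 array were 1545 for WT day 4 against day 0 (without WT day 4 replicate 2), 454 for rtcs day 2 against day 0 and 106 for rtcs day 4 against day 0 (both without rtcs day 0 replicate 4).

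With the value-table assignment, 218 probes rose and 67 fell in WT from day 0 to day 4, and 247 of these 285 changed by 2-fold or more. The split was 2267 rising and 1814 falling with slide as a fixed block and 1979 rising and 2096 falling with slide as a random block, and normexp correction gave 14 calls and the compared arrays alone 13. Replicate number as a block gave 884 rising and 556 falling, and session as a block 708 rising and 323 falling. From day 2 to day 4, 26 probes rose and 0 fell in WT. Slide as a random block gave 150 rising and 13 falling, normexp correction 1 call, leaving out 1 array 9 to 54, and the compared arrays alone 0 in limma, with 2998 at an unadjusted p under 0.05. From day 0 to day 2, 1 rose and 0 fell. That 1 probe, P1000296184 (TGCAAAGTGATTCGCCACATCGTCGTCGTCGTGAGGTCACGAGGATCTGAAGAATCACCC), rose by 2.78 on the log2 scale (SE 0.40, adjusted p = 0.049) and lost its call under 6 of the 8 alternatives run for it, with adjusted p from 0.015 to 0.97. Its log2 rise was 1.78 on normexp-corrected values and 2.75 to 2.90 in the other 5 that lost the call.

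Probe P1000227823 (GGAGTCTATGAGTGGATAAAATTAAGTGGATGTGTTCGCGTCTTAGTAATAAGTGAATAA) rose in WT from -2.93 ± 1.44 on day 0 to 2.25 ± 1.26 on day 4 (SD, n = 4), a log2 difference of 5.18 (SE 0.99, adjusted p = 0.024). In rtcs it measured -1.45 ± 2.29 and 1.39 ± 0.91 on these days. Probe P1000241608 (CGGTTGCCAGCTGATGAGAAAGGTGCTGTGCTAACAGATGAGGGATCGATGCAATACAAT) rose in WT by 5.11 (SE 1.12, adjusted p = 0.046), to 1.93 ± 1.76 on day 4, and measured -4.70 ± 0.87 in rtcs on that day. Probe P1000212742 (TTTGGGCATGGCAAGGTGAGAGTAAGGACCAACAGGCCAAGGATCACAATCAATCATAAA) fell by 2.18 in WT (SE 0.45), from 3.89 ± 0.48 to 1.72 ± 0.49, and measured 3.87 ± 0.50 and 2.87 ± 0.86 in rtcs on these days. Probe P1000272344 (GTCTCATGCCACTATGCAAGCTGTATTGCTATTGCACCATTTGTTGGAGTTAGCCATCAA) fell by 2.17 (SE 0.34, adjusted p = 0.0089), from 4.22 ± 0.19 to 2.06 ± 0.74, and measured 3.48 ± 0.31 and 2.41 ± 0.64 in rtcs. Normexp correction ended the calls of P1000227823, P1000241608 and P1000212742, with adjusted p of 0.062, 0.26 and 0.24 and log2 differences of 2.95, 2.55 and -2.13. Array weights ended that of P1000241608, with an adjusted p of 0.051 and a log2 difference of 5.11. P1000241608 was well above background on 19 of the 24 arrays and P1000227823 on 23. Some of their values outside WT days 0 and 4 are thus near background and give only a bound.

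In rtcs under the value-table assignment, limma called 0 probes for day 2 against day 0, for day 4 against day 2 and for day 4 against day 0, with 1372, 963 and 3142 probes at an unadjusted p under 0.05. Of the 285 probes called in WT for day 4 against day 0, 210 had the same sign in rtcs. Over all 285, the median log2 difference in the WT direction was 0.30 in rtcs and 2.04 in WT. The probes were chosen for passing in WT, which raises the WT value. The difference between the genotypes in day 4 against day 0, tested itself, had 0 calls, with 3736 probes at an unadjusted p under 0.05, and with slide as a random block 4 calls. With slide as a fixed block, which sets the days against each other within slides, 4081 probes were called for day 4 against day 0 in WT and 22 in rtcs, and the genotype difference of the change had 0 calls in limma, with 9099 at an unadjusted p under 0.05. The 285 calls became 30 without WT day 4 replicate 2, 50 without WT day 0 replicate 3, 60 without WT day 0 replicate 2, 128 without WT day 0 replicate 4, 181 without WT day 4 replicate 3 and 186 without WT day 4 replicate 1.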

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

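The tests of the assignments, of session, slide and scale, and of a genotype difference in the day response were chosen only after the result was seen, as were all splits and values under the value-table assignment, whole slides exchanged included, and for day 4 against day 0.

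The scanner files and the value table placed 22 of 24 arrays in different samples. Under the value-table assignment 11 of 11 slides with 2 arrays held 1 genotype on 2 days, against at most 10 in 10000 random assignments, which is what a planned layout would give and may mean that the scanner files are attached to the wrong samples. The slide barcode in each scanner file equalled that in its label for 24 of 24 files. Labels and files entered together would match in this way for any sample, so the match cannot decide. The label barcodes also ascended in 23 of 23 steps of the sample order. That the value-table columns are attached to the wrong samples stays open: 19 probes were well above background on all 12 arrays of one genotype and on none of the other, against at most 0 in 100 random splits, but with no slide holding both genotypes such probes could also mark slides, although the highest other of 100 splits that exchanged whole slides gave 1. On the first principal component the value-table genotypes lay apart, at most -3.3 in WT and at least 28.8 in rtcs. The genotype differences of days 2 and 4 correlated at 0.76 under the value-table and -0.53 under the scanner-file assignment. These values too could mark sets of slides. No transcript known to differ between the genotypes could be named, so neither assignment is settled.

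With the value-table assignment 14503 probes differed between rtcs and WT over the mean of 3 days. A shift of scale between arrays is argued against by 15368 calls on quantile-normalized values. Feature-extraction session as the whole cause would turn the difference on slides 6 and 7, whose sessions held mostly the other genotype, but the median ratio of their difference to that on the other arrays was 0.51 (0.46 to 0.60 over 4 pairs of arrays, quartiles over probes -0.05 and 1.03). Session as part of the cause stays open, since 20 other pairs of slides held out had a median of 0.72 (0.36 to 0.91). Effects of single slides as the whole cause are argued against by the splits that exchanged whole slides, with at most 5288 calls against a real 14460. A batch shared by the slides of a genotype cannot be told apart from genotype, since 0 slides held both. A genotype difference stays open as a hypothesis.

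In the value-table assignment WT had 285 calls for day 4 against day 0, and rtcs had 0 in limma, with 3142 at an unadjusted p under 0.05. The median ratio of residual SD, rtcs over WT, was 0.9, so rtcs arrays did not spread more at the median probe. The fit used the same residual SD for both genotypes at each probe, so this ratio cannot decide why the counts differed. A genotype difference in the day response had 0 calls in limma, with 3736 at an unadjusted p under 0.05, and cannot be told apart from an equal response: in the WT direction the median change was 0.30 in rtcs and 2.04 in WT, on probes chosen for passing in WT. With slide as a random block 4 probes were called for this difference and with slide as a fixed block 0, so it may be present in single transcripts, which the 0 calls without a block leave open.

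Of 102 groups of 4 arrays tested for a value far from the others, 7 had one, where chance gives about 1 in 20. On the first principal component rtcs day 4 replicate 4 lay at -64.7 under the scanner-file assignment, apart from the rest of its group. The 75th percentile of the log2 signal was 7.7 on WT day 2 replicate 3 under the value-table assignment. Probe P1000242779 measured -1.43 on rtcs day 2 replicate 4, P1000227823 0.04 on rtcs day 4 replicate 2, and P1000212742 1.78 on rtcs day 2 replicate 1, all as normalized log2 signal under the value-table assignment. Probe P1000241608 measured -0.92 on WT day 0 replicate 4 and -0.11 on WT day 2 replicate 4. The genotype difference varied between days in 180 probes under the scanner-file assignment.

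Other splits of the same arrays were counted on probes without missing values under the scanner-file assignment. For WT day 4 against day 0, 1 of 35 splits gave as many as the real 4114 calls, and the highest other gave 4. For rtcs day 2 against day 0, 1 of 35 gave as many as the real 2524, and the highest other gave 30. The lowest share that 35 splits can give is 1 of 35, and these splits exchange single arrays across slides. With slide as a random block these 2 counts were 1986 and 747. With slide as a fixed block limma called 0 for both, with 1591 and 5520 at an unadjusted p under 0.05. In the fixed-block fit only the 5 slides that held both genotypes link the groups, each by 1 array per group. Its 0 calls thus have little power and cannot decide about chance. Since the splits do not keep slides together, chance is not excluded for these 2 comparisons. Both also set WT against rtcs arrays of the value-table assignment. For the interaction 2 of 100 splits drawn gave as many as the real 179, with a highest other of 260, but these splits exchange single arrays across slides, and limma called 0 with slide as a random or fixed block, with 11371 and 4553 at an unadjusted p under 0.05, so chance is not excluded once slide is fitted. It cannot be excluded for rtcs day 4 against day 0 (2 of 35, real 1634, highest other 1780), WT day 4 against day 2 (2 of 35, real 108, highest other 252), WT day 2 against day 0 (4 of 35, real 48, highest other 1516) or rtcs against WT on day 2 (4 of 35, real 54, highest other 4264). With a real count of 0 every split gave as many: 35 of 35 for rtcs against WT on day 0 (highest other 1536) and day 4 (444), 35 of 35 for rtcs day 4 against day 2 (3839), and 100 of 100 for the mean of 3 days (1949).

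Among splits of the value-table assignment the real split alone reached its count for rtcs against WT and for WT day 4 against day 0. For rtcs against WT on day 0 the real count was 1814 (1 of 35 splits, highest other 7). It was 583 on day 2 (1 of 35, highest other 3) and 2633 on day 4 (1 of 35, highest other 0). Over the mean of 3 days it was 14460 (1 of 100, highest other 203). For WT day 4 against day 0 it was 286 (1 of 35, highest other 22). A share of 1 of 35 is the lowest that 35 splits can give. Chance cannot be excluded for WT day 2 against day 0 (7 of 35, real 1, highest other 20) or WT day 4 against day 2 (2 of 35, real 26, highest other 32). With a real count of 0 every split gave as many: 35 of 35 for rtcs day 2 against day 0 (highest other 7), rtcs day 4 against day 2 (98) and rtcs day 4 against day 0 (3), and 100 of 100 for the interaction (172). These splits exchange single arrays. When whole slides were exchanged instead, 1 of 100 splits, the real one alone, gave as many as the real count in each of 7 tests. The highest other was 81 for day 0 (real 1814), 2 for day 2 (real 583), 366 for day 4 (real 2633) and 5288 for the mean of 3 days (real 14460). It was 0 for probes called on all 3 days (real 298), 34 for called probes whose genotypes did not overlap (real 339) and 1 for probes well above background in 1 genotype alone (real 19). Neither kind of split parts genotype from session or from a batch shared by the slides of a genotype.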

How the results depend on the processing

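The value-table assignment, day 4 against day 0, session as a block, single sessions, slides left out and all values of named probes were alternatives chosen only after the result was seen. The signal limits what a dim probe shows, since 57.5% to 70.8% of probes per array were well above background. By the rule fixed before the data were examined, that every pair of arrays with the same replicate number correlates at over 0.1, the numbers were not used to pair the samples. With the scanner-file assignment 10 of 60 pairs with the same number passed (mean -0.05) and 54 of 180 with other numbers (mean 0.02). With the value-table assignment 32 of 60 passed (mean 0.15) and 32 of 180 with other numbers (mean -0.05), and 18 of 24 arrays correlated best with an array of their own number. On different slides the means were 0.12 and -0.05, so under that assignment arrays of 1 number shared some variation, and replicate as a block gave 1440 for WT day 4 against day 0, against 285 without it, and 3540 for rtcs against WT on day 0, against 1816. Counting 1 probe per gene and the gene list tests were not run, because no probe could be named. Slide as a fixed block could not be fitted to the genotype comparisons under the value-table assignment. The value table as deposited was used up to row 53236, with columns by their own names and no filter. Of 72 values of named probes under alternatives, 62 kept their direction and call, 10 lost the call and 0 turned. These cover 8 alternatives, and the named probes were not refitted with slide as a block, with only the arrays compared or with an array left out.

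The counts below moved under the scanner-file assignment, and the cause was not tested. The highest leave-one-out counts for the interaction and for rtcs against WT day 2 came without WT day 2 replicate 4. Those for rtcs day 4 against 0 and against 2 came without rtcs day 4 replicate 4. The value table gave each of these arrays to the genotype opposite to the rest of its group. Quantile normalization gave 2 for rtcs against WT day 0, 16 for rtcs against WT day 2, 8 for the interaction and 170 for WT day 2 against 0. Median centring gave 0 for the interaction, 107 for WT day 2 against 0, 60 for WT day 4 against 2 and 2766 for rtcs day 4 against 0. The percentile over probes well above background on all arrays gave 35 for rtcs against WT day 2, 51 for the interaction, 16 for WT day 4 against 2 and 1074 for rtcs day 4 against 0. Normexp background correction gave 0 for rtcs against WT day 2, 42488 for rtcs against WT over the mean of 3 days, 0 for the interaction, 1 for rtcs day 2 against 0, 420 for WT day 4 against 0 and 0 for rtcs day 4 against 0. The value table as deposited carries the value-table assignment by its column names, so that its counts differ in assignment as well as in source. It gave 567 for rtcs against WT day 0, 250 for rtcs against WT day 2, 917 for rtcs against WT day 4, 6742 for rtcs against WT over the mean of 3 days, 1 for the interaction, 0 for WT day 2 against 0, 10 for WT day 4 against 2, 0 for rtcs day 2 against 0, 74 for WT day 4 against 0 and 0 for rtcs day 4 against 0. Testing without a filter on dim probes gave 2 for the interaction, 19 for WT day 4 against 2, 1650 for rtcs day 2 against 0 and 549 for rtcs day 4 against 0. Testing probes well above background on all 24 arrays gave 3 for rtcs against WT day 2, 793 for the interaction, 11 for WT day 2 against 0 and 53 for WT day 4 against 2. Slide as a random block gave 5 for rtcs against WT day 2, 0 for the interaction, 3 for WT day 2 against 0, 8 for WT day 4 against 2, 747 for rtcs day 2 against 0, 1986 for WT day 4 against 0 and 368 for rtcs day 4 against 0. Slide as a fixed block gave 0 for rtcs against WT day 2, 11 for rtcs against WT day 4, 0 for the interaction, 0 for WT day 2 against 0, 1 for WT day 4 against 2, 0 for rtcs day 2 against 0, 1 for rtcs day 4 against 2, 0 for WT day 4 against 0 and 0 for rtcs day 4 against 0. Replicate number as a block gave 10 for rtcs against WT day 2, 2 for the interaction, 24 for WT day 2 against 0, 12 for WT day 4 against 2, 1404 for rtcs day 2 against 0 and 718 for rtcs day 4 against 0. Fitting the arrays compared alone gave 0 for rtcs against WT day 2, 0 for WT day 2 against 0, 7 for WT day 4 against 2, 1020 for rtcs day 2 against 0 and 0 for rtcs day 4 against 0. Array weights gave 7042 for rtcs against WT day 2, 7825 for rtcs against WT day 4, 23 for rtcs against WT over the mean of 3 days, 14101 for the interaction, 1669 for WT day 2 against 0, 12935 for WT day 4 against 2, 8628 for rtcs day 2 against 0, 4803 for rtcs day 4 against 2, 7931 for WT day 4 against 0 and 13802 for rtcs day 4 against 0. A trended, robust prior gave 814 for the interaction and 194 for WT day 4 against 2. Extraction session as a block gave 530 for rtcs against WT day 2, 1 for rtcs against WT day 4, 773 for the interaction, 334 for WT day 2 against 0, 269 for WT day 4 against 2, 2241 for rtcs day 4 against 2 and 1120 for WT day 4 against 0. Leaving out 1 array at a time gave 0 to 10 for rtcs against WT day 0, 0 to 44 for rtcs against WT over the mean of 3 days, 0 to 5722 for the interaction, 4 to 2037 for WT day 2 against 0, 1545 to 4298 for WT day 4 against 0, 454 to 3634 for rtcs day 2 against 0, 106 to 5585 for rtcs day 4 against 0, 2 to 5380 for rtcs against WT day 2, 2 to 3394 for WT day 4 against 2, 0 to 1142 for rtcs day 4 against 2 and 0 to 1 for rtcs against WT day 4.

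The following counts under the value-table assignment moved, apart from ranges that stayed at 0, and the cause was not tested. Quantile normalization gave 2 for the interaction and 0 for WT day 2 against 0. Median centring gave 1 for the interaction and 0 for WT day 2 against 0. Normexp background correction gave 29 for rtcs against WT day 0, 25 for rtcs against WT day 2, 112 for rtcs against WT day 4, 2447 for rtcs against WT over the mean of 3 days, 0 for WT day 2 against 0, 1 for WT day 4 against 2 and 14 for WT day 4 against 0. Testing without a filter on dim probes gave 1041 for rtcs against WT day 0, 0 for WT day 2 against 0 and 140 for WT day 4 against 0. Testing probes well above background on all 24 arrays gave 262 for rtcs against WT day 2, 8 for WT day 4 against 2 and 1 for rtcs day 4 against 2. Slide as a random block gave 4106 for rtcs against WT day 4, 7915 for rtcs against WT over the mean of 3 days, 6 for the interaction, 163 for WT day 4 against 2, 1 for rtcs day 4 against 2, 4075 for WT day 4 against 0 and 2 for rtcs day 4 against 0. Slide as a fixed block gave 0 for WT day 2 against 0, 4081 for WT day 4 against 0 and 22 for rtcs day 4 against 0. Replicate number as a block gave 3540 for rtcs against WT day 0, 920 for rtcs against WT day 2, 4586 for rtcs against WT day 4, 0 for WT day 2 against 0, 78 for WT day 4 against 2 and 1440 for WT day 4 against 0. Fitting the arrays compared alone gave 111 for rtcs against WT day 0, 1582 for rtcs against WT day 4, 0 for WT day 2 against 0, 0 for WT day 4 against 2 and 13 for WT day 4 against 0. Array weights gave 2582 for rtcs against WT day 2, 7048 for rtcs against WT day 4, 2 for the interaction, 44 for WT day 4 against 2, 1 for rtcs day 4 against 2 and 524 for WT day 4 against 0. Extraction session as a block gave 268 for rtcs against WT day 2, 1041 for rtcs against WT day 4, 8873 for rtcs against WT over the mean of 3 days, 0 for WT day 2 against 0, 15 for WT day 4 against 2 and 1031 for WT day 4 against 0. Leaving out slides 6 and 7 gave 734 for rtcs against WT day 0, 2 for the interaction, 4 for WT day 2 against 0, 48 for WT day 4 against 2 and 2 for rtcs day 4 against 2. Leaving out slide 13 gave 363 for rtcs against WT day 2, 0 for WT day 2 against 0 and 16 for WT day 4 against 2. Session 1 alone gave 858 for rtcs against WT, with rtcs arrays of days 0 and 2 from slide 7 alone. Session 2 alone gave 1322 for rtcs against WT, with WT arrays of days 2 and 4 from slide 6 alone. Leaving out 1 array at a time gave 751 to 2901 for rtcs against WT day 0, 12104 to 15204 for rtcs against WT over the mean of 3 days, 0 to 3 for the interaction, 0 to 3 for WT day 2 against 0, 30 to 404 for WT day 4 against 0, 1009 to 2345 for rtcs against WT day 4, 9 to 54 for WT day 4 against 2, and 263 to 532 for rtcs against WT day 2. It left rtcs day 2 against 0, rtcs day 4 against 0 and rtcs day 4 against 2 at 0 with every array left out.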

Other observations

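The comparison of probes that share sequence used the value-table assignment, which was chosen after the data were seen, while its prediction was written before its result was seen. Pairs of different probes that shared 25 to 50 bases on the same strand numbered 2374. Their rtcs minus WT differences correlated at 0.85 across pairs and their mean levels at 0.90, against 0.01 and 0.02 in 2374 random pairs. Both probes were called in 312 of these pairs, and 310 of them had the same direction. In random pairs 29 of 75 had the same direction. The value of 0.85 is consistent with overlapping probes reading 1 transcript, as a hypothesis.

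Pairs that shared sequence on opposite strands numbered 1170. Their mean levels correlated at -0.12 and their rtcs minus WT differences at 0.55, and 97 of 103 pairs with both probes called had the same direction. Probes and pairs are not independent replicates.

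The median GC content was 45% for probes higher in rtcs, for probes lower in rtcs and for tested probes without a call under the value-table assignment. The means were 49.1%, 45.9% and 48%.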
